A study of Mus musculus with 22 samples.

How the data were processed

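RNA from liver and from 3 populations of spermatogenic cells of male mice aged 2 months was measured on 22 Affymetrix arrays. The cells were sorted by flow cytometry into pre-mid-pachytene spermatocytes, mid-late-pachytene spermatocytes and spermatids. Ts43H males carry an extra copy of the centromeric part of chromosome 17, and their t121/D17 siblings are euploid. Biotinylated RNA was prepared from 20 to 30 ng of total RNA by a labelling protocol of 2 cycles. Each genotype had 3 arrays of liver, of pre-mid-pachytene spermatocytes and of spermatids, and 2 arrays of mid-late-pachytene spermatocytes. The labels do not say whether the arrays of a group came from separate animals.

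The deposited values are log2 intensities per probe set that the authors computed with GCRMA, whose version is not given, and which arrays were normalized together is not stated. GCRMA subtracts a background estimated from GC content, sets the arrays to a common distribution and summarizes the probes of each probe set. The table held 16539 probe sets without missing values, of which 15780 carried 1 gene symbol each. The other 759 carried no name and were not used here for the gene tests. Gene order was taken from a gene table of the mouse assembly GRCm38.p6, which matched 15752 of the named genes, while 28 could not be placed. Values ran from 0.90 to 16.75, array medians from 4.10 to 4.69 and lower quartiles from 2.35 to 2.46. Values below 3 are called the background range. The number of arrays, not a count of molecules, limits the precision.

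The breakpoint of the extra segment is not given in the labels, so the trisomic segment was set to the first 30 Mb of chromosome 17, from Scaf8 to Mdga1, with 252 genes on the array. Distal chromosome 17 was set to start at 45 Mb, at Cdc5l, with 284 genes, and the 207 genes between were in neither region. The tip of chromosome 16 was set to its last 3 Mb, because the marker chromosome of Ts43H arose from a translocation between chromosomes 16 and 17.

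Changed genes were called with limma 3.58.1 in R 4.3.3, with statmod 1.5.0 and python 3.11.15 for other steps. The 8 group means of all 22 arrays were fitted together, so that every comparison shared 1 estimate of the spread per gene, moderated across genes by limma. Trisomic was compared with euploid within each cell type, over genes with a mean of at least 4 in that cell type, by two-sided tests with Benjamini-Hochberg adjustment at 0.05. A regional score was the median over a region's genes, with a mean of at least 6 in the cell type, of each gene's deviation from its mean in that cell type, minus the same median over the autosomes except chromosome 17. The scores of 22 regions were compared with limma in the same way, with 95% confidence intervals, and differences between cell types were tested as interaction terms. A whole-chromosome score of chromosome 16 was added as a result of its own after the values had been seen.

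Gene lists were tested with camera of the limma package, which compares the genes of a list with all other genes, at a preset correlation of 0.01. All 36 lists, 13 of cell type markers and 23 of pathways, were fixed beforehand, and those with at least 5 tested genes gave 105 tests over the 4 cell types, adjusted together. A second run of camera estimated the correlation between the genes of each list. The tested genes of the trisomic segment were compared with camera in both ways as well, without adjustment. The p values of fry test whether a list's genes move on balance in 1 direction, and its mixed p values whether they change in either direction, and neither compares the list with other genes. Enrichments used two-sided and overlaps one-sided Fisher's exact tests, over the genes tested in the comparison or in both comparisons. These tests take the genes as independent, which genes measured on the same arrays are not. For an extra look at cell stage, changes along the differences between the germ cell types of the euploid arrays were regressed out of the germ cell changes.

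The genes named in the text follow a rule. Per cell type, and among genes past the threshold whose trisomic and euploid arrays did not overlap, these are the 8 largest increases and the 8 largest decreases outside the segment and up to 6 increases and 3 decreases within it. For each list, up to 4 members past the threshold were named, or 2 of the members with the highest mean where none passed. Genes outside this rule are said to be chosen after their values were seen.

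The groups, comparisons, lists, naming rule, region bounds and the alternatives not described as added were chosen before the data were examined. The alternatives were no filter or a minimum mean of 4, 6 or 8, quantile normalization between all arrays, centring each array on its autosomal median, limma with a trend and robust spread, the arrays of the compared cell types only, each probe set on its own, segment ends at 25 or 35 Mb, the mean in place of the median, genes scored in both cell types, the replicate number as a block, an estimated correlation for the lists, and leaving out each array in turn. The mean of the round spermatid markers of each array as a covariate for stage was added later. In mid-late-pachytene spermatocytes, leaving out an array left 1 array in a group, which was then assumed to vary like the other groups.

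The fits were tested on simulated data with 100 genes changed by 1 and 100 by 2 on the log2 scale. In liver 64% of the former and 95% of the latter were recovered, and 63% and 93% in pre-mid-pachytene spermatocytes. Recovery was 41% and 89% in mid-late-pachytene spermatocytes and 63% and 96% in spermatids. False calls made up 4.93%, 4.74%, 6.25% and 7.76% of the calls in the same order. The simulated noise was drawn independently for each gene and array, with 1 spread per gene over all groups, as the fit assumes. These shares therefore do not cover correlated genes or a spread that differs between cell types. A simulated segment shift of 0.585 was recovered as 0.59, 0.56, 0.59 and 0.58.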

Results

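The 22 arrays compared trisomic with euploid males in liver (3 arrays of each genotype), pre-mid-pachytene spermatocytes (3 and 3), mid-late-pachytene spermatocytes (2 and 2) and spermatids (3 and 3). Within a genotype the arrays of a cell type correlated across genes with r between 0.988 and 0.997, where genes are not independent replicates. Hepatocyte markers had a median level of 15.66 ± 0.11 (log2, SD, n = 3) in euploid liver and lay between 2.33 and 2.45 in every germ cell group. Early meiotic prophase markers reached 12.47 ± 0.12 (SD, n = 3) in euploid pre-mid-pachytene spermatocytes. They had 9.65 ± 0.25 (SD, n = 2) in euploid mid-late-pachytene spermatocytes and 11.31 ± 0.14 (SD, n = 3) in euploid spermatids. Pachytene spermatocyte markers had 11.39 ± 0.18, 13.64 ± 0.10 and 13.24 ± 0.25 in the same order and with the same n. Neither list was low in spermatids. Round spermatid markers reached 13.59 ± 0.16 (SD, n = 3) in euploid spermatids, against 10.50 ± 0.45 (SD, n = 3) in the pre-mid-pachytene and 9.84 ± 1.02 (SD, n = 2) in the mid-late-pachytene euploid arrays. Elongating spermatid markers had a median of 14.60 ± 0.17 (SD, n = 3) in euploid spermatids and 10.42 ± 1.05 (SD, n = 2) in euploid mid-late-pachytene spermatocytes. In euploid pre-mid-pachytene spermatocytes they reached 13.75 ± 0.19 (SD, n = 3). Markers of Sertoli cells, the supporting cells of the tubule, had a median of 6.78 ± 0.26 (SD, n = 3) in euploid pre-mid-pachytene spermatocytes and 4.29 ± 0.51 (SD, n = 3) in euploid spermatids. The 4 red blood cell markers on the array were too few to test.

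The main question of the series was how far an extra copy of part of chromosome 17 raises the expression of its genes in germ cells, with liver as the somatic counterpart. In liver the genes of the trisomic segment rose together by 0.70 on the log2 scale relative to the other autosomes (SE 0.038, 114 genes). This is a fold of 1.63, whose 95% confidence interval of 1.54 to 1.72 lies above the 1.5 of 3 copies over 2. The euploid siblings carry the label t121/D17. Whether the genotypes also differ in the sequence of the segment under the probes was not tested. The segment also rose in mid-late-pachytene spermatocytes, by 0.31 (SE 0.047, 116 genes, fold 1.24, interval 1.16 to 1.33), and in spermatids, by 0.35 (SE 0.038, 122 genes, fold 1.28, interval 1.21 to 1.35). Pre-mid-pachytene spermatocytes showed a shift of 0.11 (SE 0.038, 123 genes, fold 1.08, interval 1.02 to 1.14) that did not pass over the 22 regions. Adjusted p values were 9.7e-11 in liver, 1.5e-04 in mid-late-pachytene spermatocytes, 2.0e-06 in spermatids and 0.0777 in pre-mid-pachytene spermatocytes. The pre-mid-pachytene shift passed when genes with a mean of at least 4 were scored (0.13, adjusted p = 0.0411), with the mean over genes (0.15, adjusted p = 0.0181) and without euploid pre-mid-pachytene replicate 3 (0.14, adjusted p = 0.0231), and was 0.07 without trisomic replicate 3.

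Where it passed, the rise was spread over most genes of the segment. In liver 108 of 114 scored segment genes (94.7%) lay above the median change of the reference autosomes, against 93.4% in spermatids, 89.7% in mid-late-pachytene spermatocytes and 57.7% in pre-mid-pachytene spermatocytes. Every trisomic liver array lay between 0.67 and 0.73 above the euploid mean. Trisomic arrays lay at 0.28 and 0.34 in mid-late-pachytene spermatocytes, at 0.27, 0.39 and 0.40 in spermatids, and at 0.07, 0.07 and 0.19 in pre-mid-pachytene spermatocytes. The shift was smaller than in liver by a test of the difference itself in all 3 germ cell types: -0.59 in pre-mid-pachytene spermatocytes (95% interval -0.71 to -0.48, adjusted p = 1.9e-07), -0.40 in mid-late-pachytene spermatocytes (-0.52 to -0.27, adjusted p = 1.5e-04) and -0.35 in spermatids (-0.46 to -0.24, adjusted p = 1.7e-04). Among the germ cells, the shift was larger in spermatids than in pre-mid-pachytene spermatocytes by 0.24 (SE 0.054, adjusted p = 0.00529). The differences of mid-late-pachytene spermatocytes to pre-mid-pachytene spermatocytes (0.20, adjusted p = 0.0527) and of spermatids to mid-late-pachytene spermatocytes (0.05, adjusted p = 0.949) did not pass.

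**Figure D1:**
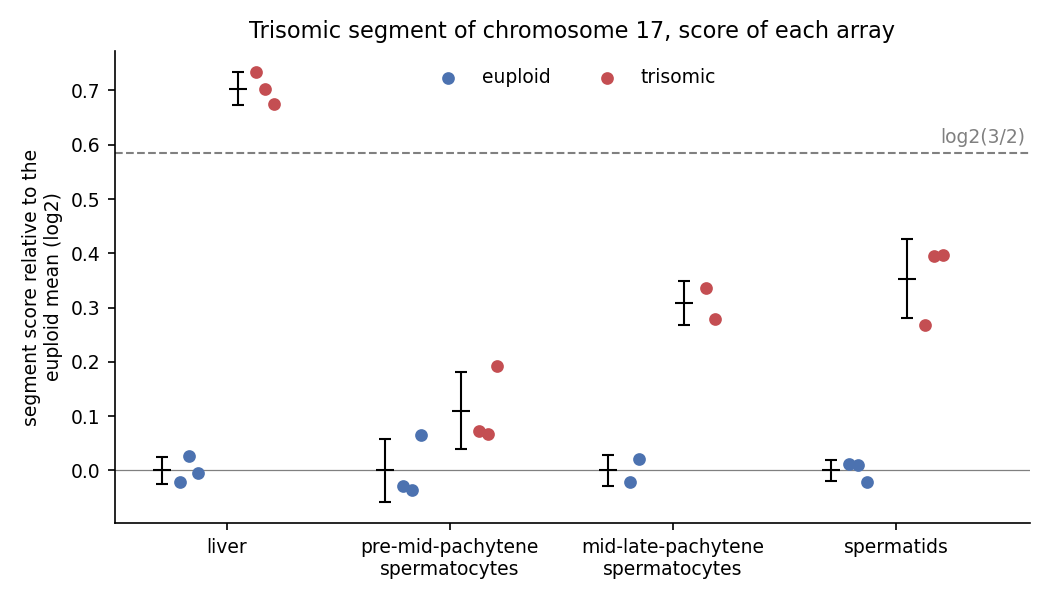
Regional score of the trisomic segment on each array (points), relative to the euploid mean of its cell type, on the log2 scale. Black bars give the mean and SD of the 3 arrays of a group (2 in mid-late-pachytene spermatocytes), and the dashed line marks log2 of 3 over 2, at 0.58. The trisomic liver arrays lie above that line and the trisomic germ cell arrays, at 0.07 to 0.40, below it.

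The rest of the affected chromosomes was compared in the same way. Distal chromosome 17, present in 2 copies, had shifts of -0.03 in liver (adjusted p = 0.77), -0.03 in pre-mid-pachytene spermatocytes, 0.03 in mid-late-pachytene spermatocytes and 0.01 in spermatids, none past the threshold. The few scored genes at the tip of chromosome 16 had shifts of 0.12, -0.09, -0.09 and -0.16 in the same order, and none passed. Chromosome 16 as a whole fell by 0.22 in trisomic pre-mid-pachytene spermatocytes (SE 0.023, 210 genes, adjusted p = 9.0e-07) and by 0.08 in spermatids (SE 0.023, adjusted p = 0.0252). Its shifts of -0.08 in mid-late-pachytene spermatocytes (adjusted p = 0.085) and 0.04 in liver (adjusted p = 0.371) did not pass. In the extra look with the stage differences regressed out, the mid-late-pachytene shift was -0.12 (SE 0.028, limma adjusted p = 0.00807). Of the 268 tested chromosome 16 genes, 29 fell and 5 rose in pre-mid-pachytene spermatocytes. These were more falling genes than elsewhere (Fisher's exact p = 1.2e-05, with the genes taken as independent). The 5 rising genes, chosen after their values were seen, were Lmln, Usp25, Cbr1, Pdxdc1 and Chmp2b. The segment in 3 cell types and chromosome 16 in 2 were the regions past the threshold.

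**Figure D2:**
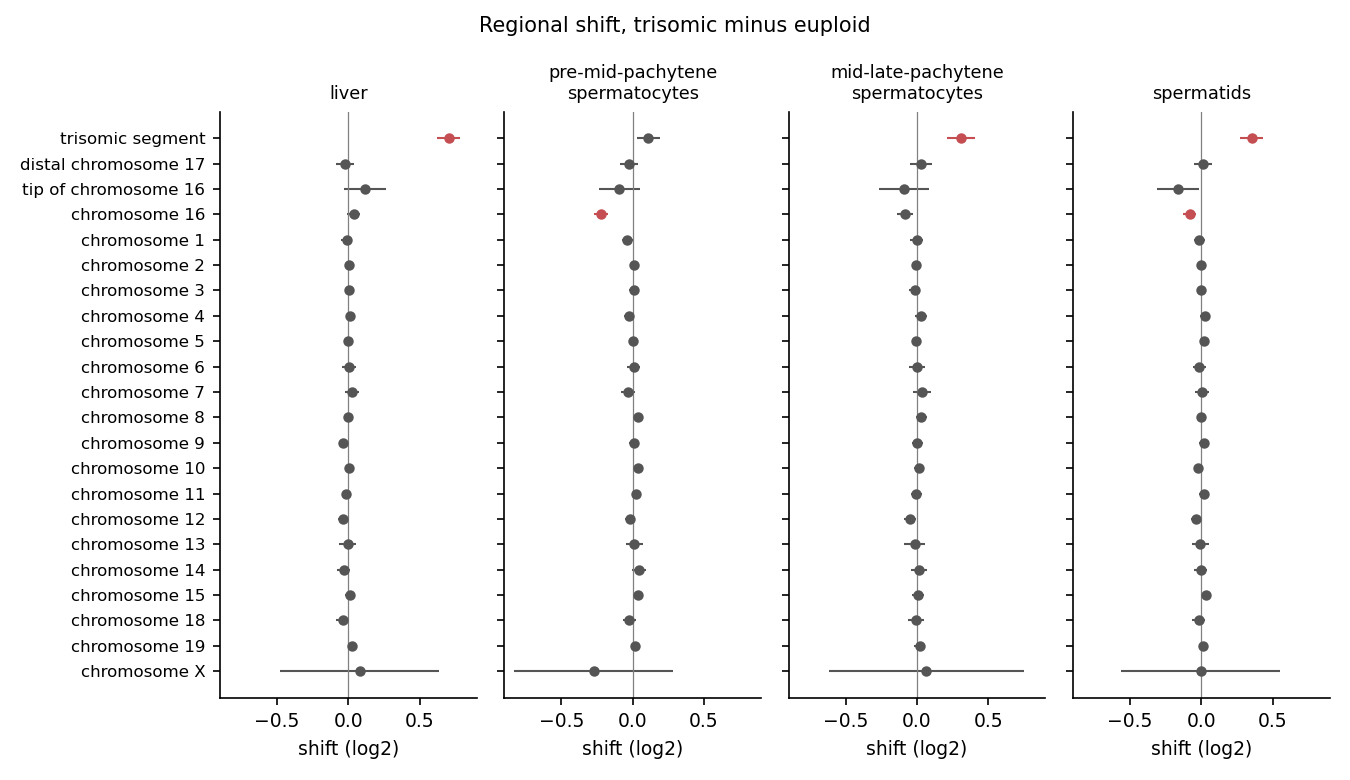
Shift of each of the 22 regions, trisomic minus euploid, on the log2 scale in the 4 cell types, with 95% confidence intervals as horizontal bars. Red points passed the adjusted threshold of 0.05: the trisomic segment in liver, mid-late-pachytene spermatocytes and spermatids, and chromosome 16 in pre-mid-pachytene spermatocytes and spermatids.

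The fall of chromosome 16 was graded along the chromosome. With the scored genes ordered from the centromere and divided into 4 groups of similar size, a division chosen after the values were seen, the shifts in pre-mid-pachytene spermatocytes were -0.63 (SE 0.084, 52 genes from Zfp263 to Spag6l, 43 of them lower), -0.26, -0.15 and 0.0088. Mid-late-pachytene spermatocytes had shifts of -0.28 (SE 0.051), -0.09, -0.08 and 0.03 from the centromere outward. The same order in spermatids gave -0.24 (SE 0.014, 44 of 54 genes lower), -0.10, -0.01 and 0.02. Liver had 0.08 (SE 0.068), 0.0059, -0.02 and 0.05.

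**Figure D3:**
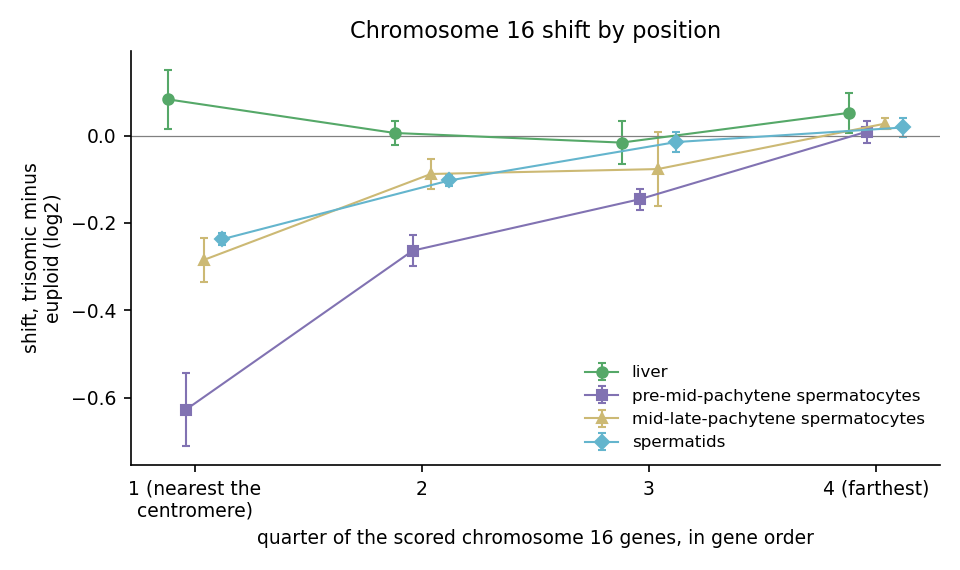
Shift of chromosome 16 genes, trisomic minus euploid, on the log2 scale, in 4 groups of genes ordered from the centromere, with bars of 1 SE from the arrays of each cell type. In the germ cells the shift is lowest nearest the centromere (-0.63, -0.28 and -0.24) and near 0 in the farthest group, while in liver it lies between -0.02 and 0.08.

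The X chromosome is silenced in pachytene, and its score was compared because failed pairing of other chromosomes can go with a change in that silencing. In euploid arrays the median level of the X genes differed from that of the autosomal genes by -0.92 ± 0.04 in pre-mid-pachytene spermatocytes, -5.06 ± 0.03 in mid-late-pachytene spermatocytes, -2.78 ± 0.18 in spermatids and -1.20 ± 0.04 in liver (SD, n = 3, and n = 2 in mid-late-pachytene spermatocytes). The trisomic arrays had -1.15 ± 0.28, -5.04 ± 0.14, -3.01 ± 0.11 and -0.96 ± 0.03 in the same order and with the same n. In liver the arrays of the genotypes did not overlap in this untested quantity (-1.24 to -1.17 in euploids, -0.99 to -0.93 in trisomics). The tested score differs from it, since it takes the genes with a mean of at least 6 and the median of their deviations from the mean of the cell type. In that score the trisomic arrays differed from the euploid ones by -0.27 in pre-mid-pachytene spermatocytes (SE 0.263, adjusted p = 0.502), 0.06 in mid-late-pachytene spermatocytes (SE 0.323, adjusted p = 0.941), -0.0049 in spermatids (adjusted p = 0.989) and 0.08 in liver (adjusted p = 0.906). None of these passed, and intervals of -0.83 to 0.29 in pre-mid-pachytene and -0.62 to 0.75 in mid-late-pachytene spermatocytes leave room for changes of either sign. Euploid pre-mid-pachytene X genes lay no lower against the autosomes than those of liver (-0.92 and -1.20), so their score says little about silencing. In mid-late-pachytene spermatocytes the score covers only 35 X genes and leaves out those with lower means. No conclusion about silencing is therefore drawn from these scores. The pre-mid-pachytene shift was -0.11 without trisomic pre-mid-pachytene replicate 2 and -0.45 without trisomic replicate 3, and that in spermatids ranged from -0.12 (without euploid spermatid replicate 2) to 0.10 (without euploid replicate 3). The euploid mid-late-pachytene arrays lay far apart (SD 1.10 over 35 genes): the shift became 0.84 without euploid replicate 1 (adjusted p = 0.0106) and -0.71 without euploid replicate 2 (adjusted p = 0.0385). Fitted on the liver arrays alone, the liver shift of 0.08 passed (adjusted p = 0.0270). In pre-mid-pachytene spermatocytes 18 X genes fell and 2 rose (Nbdy and Col4a5, chosen after their values were seen) of 244 tested, on arrays whose round spermatid markers also fell.

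Trisomic liver differed from euploid liver in 781 of 8180 genes, of which 472 rose and 309 fell, and 1816 genes had an unadjusted p under 0.05. Of the 144 tested segment genes 68 rose and 0 fell in limma (Fisher's exact p = 1.2e-46). Among them Smoc2, a secreted matrix protein, rose by 3.05 (log2, SE 0.45, adjusted p = 2.5e-04). Dll1, a Notch ligand, rose by 2.09, Nthl1, a DNA glycosylase of base excision repair, by 1.79, Bnip1 by 1.74 and Ift140, a part of intraflagellar transport, by 1.71. Msln rose by 1.99, and by 1.28 without euploid liver replicate 3. Outside the segment, H19, an imprinted noncoding RNA of fetal liver, rose by 7.80 (SE 0.83, adjusted p = 1.1e-05), from 2.16 ± 0.07 in the background range to 9.96 ± 1.98 (SD, n = 3 each). Sult1e1, the oestrogen sulfotransferase, rose by 7.59 (SE 0.16, adjusted p = 6.0e-16), from a euploid level of 2.41 ± 0.25 (SD, n = 3) in the background range. Hao2 rose by 5.63, also from the background range (2.49 ± 0.30, SD, n = 3), Slc22a27 by 4.89 and Slc22a29 by 4.66. Decreases included those of Serpina4-ps1 (-6.65, SE 0.81, adjusted p = 3.9e-05), Nat8 (-5.15), Serpina12, which encodes vaspin (-4.86, SE 0.28, adjusted p = 7.7e-09), and Nat8f5 (-4.18). Fitted on the liver arrays alone, 19 genes passed, H19, Sult1e1, Serpina12 and Gstm3 among them.

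Genes whose liver expression depends on sex were among the largest changes. Their SEs and calls use 1 spread per gene shared by all cell types, not that of the liver arrays alone. The SD of the 3 trisomic liver arrays was 3.78 for Cyp2b13 and 4.86 for Hsd3b5. Of 6 tested female-biased genes 4 rose and 2 did not pass, with a median change of 3.84: the cytochrome P450 genes Cyp2b13 (7.79, SE 1.05, adjusted p = 1.1e-04, with a euploid level of 1.84 in the background range), Cyp2b9 (7.51, SE 1.03) and Cyp2b10 (2.80), and the acyl-CoA thioesterase gene Acot3 (4.88, SE 0.70). Of 11 male-biased genes 7 fell and 4 did not pass, with a median of -3.04, among them Ugt2b38 (-5.54, SE 0.75), the complement gene C6 (-4.46, SE 0.63) and the steroid hydroxylase gene Cyp7b1 (-3.04, SE 0.34). Adjusted over the list alone, 4 of the 17 genes rose and 10 fell. Since the members moved apart, the list as a whole did not pass camera (adjusted p = 0.19), while the mixed test of fry gave an adjusted p of 2.1e-05. Hsd3b5 fell by 5.95 (SE 1.36) and by 3.16 without trisomic liver replicate 2, and Slco1a1 fell by 4.65 and by 1.88 without that array. Slco1a1 did not pass without euploid liver replicate 1 (adjusted p = 0.0751) or 3 (adjusted p = 0.125). Cyp2b10 was at 2.16 without trisomic replicate 2 (adjusted p = 0.154), at 3.01 without trisomic replicate 3 (adjusted p = 0.0507) and at 1.27 without euploid replicate 3 (adjusted p = 0.0547), so its call rested on each of these. Over the set, trisomic replicate 2 lay farthest out, with medians of 3.53 for the female-biased and -4.25 for the male-biased genes relative to the liver mean, against 0.58 and 1.65, and 0.01 and -0.03, on the other 2 trisomic arrays. Euploid replicate 2 lay closest to the trisomic arrays among the euploids (-0.61 and 0.48). Without trisomic replicate 2, 3 female-biased genes rose and 7 male-biased genes fell, with medians of 3.03 and -1.88. Only 4 male-biased genes fell without euploid liver replicate 1 or 3, against 8 without euploid replicate 2 or trisomic replicate 1 or 3, and 3 female-biased genes rose without euploid replicate 3 or trisomic replicate 3.

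**Figure D4:**
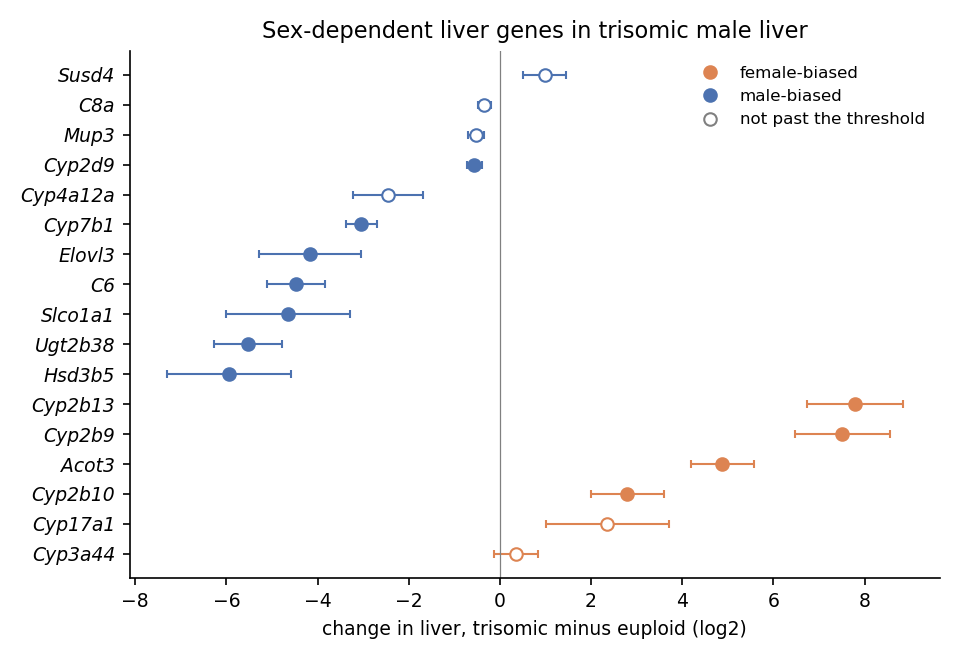
Change of the 17 tested sex-dependent genes in liver, trisomic minus euploid, on the log2 scale, for 3 arrays of each genotype. Bars give 1 SE from limma, whose spread per gene was estimated over the arrays of all cell types, not of liver alone. Filled points passed the adjusted threshold: 4 female-biased genes rose and 7 male-biased genes fell.

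Of the 28 lists tested in liver, 10 passed camera, 8 upward and 2 downward, and none of them with an estimated correlation, where the lowest adjusted p was 0.148. Genes of cell cycle and DNA replication rose: 5 of 10 passed and 0 fell (7 and 0 adjusted over the list alone), with a median of 1.59, among them the replicative helicase genes Mcm6 (3.43) and Mcm5 (2.76). The mitotic activator gene Cdc20 rose by 4.41 from a euploid level of 2.49, and Cdk1 by 3.13 from 2.82, both in the background range, so the size of these changes depends on the floor of the array. The change of Cdk1 was 2.07 without trisomic liver replicate 3. The list had an adjusted p of 1.6e-06, and an adjusted p = 0.434 with an estimated correlation. The heat shock and unfolded protein response list fell: 8 of 26 genes passed downward and 0 upward (10 and 1 adjusted over the list alone), with a median of -0.39, among them the endoplasmic reticulum factors Sdf2l1 (-1.71), Creld2 (-1.24) and Dnajb11 (-1.08). Its adjusted p was 1.9e-05, and adjusted p = 0.148 with an estimated correlation. Fatty acid oxidation rose in 6 of 20 genes and fell in 0 (6 and 0 adjusted over the list alone), with a median of 0.27, led by the omega-hydroxylase genes Cyp4a31 (3.04) and Cyp4a14 (2.47), with an adjusted p of 0.00344, or adjusted p = 0.148 with an estimated correlation. Among genes of fatty acid synthesis and storage 3 of 15 rose, Cd36 (2.24), Scd1 (0.98) and Fads2 (0.56), with 6 up and 1 down adjusted over the list alone and an adjusted p of 0.0158, or adjusted p = 0.594 with an estimated correlation. That list did not pass without euploid liver replicate 2 or 3 or trisomic replicate 3 (adjusted p up to 0.219), and Fads2 did not without euploid replicate 2 or trisomic replicate 1 or 2 (adjusted p up to 0.0922).

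Further lists passed in liver. Of 7 t complex genes, all in the segment, 3 rose (4 adjusted over the list alone), Igf2r by 1.14 and Sod2 by 0.67 among them, with a median of 0.67 and an adjusted p of 0.00618. Peritubular and stromal markers rose in 2 of 7 genes (3 adjusted over the list alone), led by the collagen gene Col1a2 (1.66), with a median of 0.78 and an adjusted p of 0.00618 as well. Both had an adjusted p = 0.148 with an estimated correlation. Xenobiotic metabolism rose on balance, with 4 of 22 genes up and 1 down (6 and 1 adjusted over the list alone), among them Nqo1 (1.63), Gstm3 (1.34) and Ces2a (-0.42). Its adjusted p was 0.0183, or 0.0579 without trisomic liver replicate 2, and adjusted p = 0.529 with an estimated correlation. Circadian clock genes fell in 2 of 13 cases (3 adjusted over the list alone), Usp2 by 1.55 and Per1 by 1.90, or by 1.23 without trisomic replicate 2. The list had an adjusted p of 0.0183, or 0.0516 without euploid replicate 2, and adjusted p = 0.148 with an estimated correlation. Macrophage and leukocyte markers rose in 2 of 15 genes, with a median of 0.40 and an adjusted p of 0.0228 (adjusted p = 0.656 with an estimated correlation). Both genes, H2-Aa and H2-Ab1, lie on chromosome 17 between the trisomic segment and the distal part. Since the breakpoint is not given, whether they have an extra copy is not known. Of these H2-Aa rose by 1.19, or by 0.69 without trisomic liver replicate 2, and did not pass without euploid replicate 3 (adjusted p = 0.0509). The list did not pass at a minimum mean of 6 (adjusted p = 0.0523) or without euploid replicate 2 or 3 or trisomic replicate 1 or 2 (adjusted p up to 0.369). Oxidative phosphorylation passed with a median of 0.13 and 1 of 34 genes up, Ndufb10 (0.90), which lies in the segment. Its adjusted p was 0.0330, or 0.723 with an estimated correlation, 0.0663 after quantile normalization and up to 0.149 without euploid replicate 2 or 3 or trisomic replicate 1 or 2.

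Several liver lists changed in single members without passing as a whole. Bile acid and sterol metabolism had 2 of 20 genes up and 3 down (2 and 6 adjusted over the list alone; adjusted p = 0.368; fry mixed adjusted p = 6.7e-13), among them Cyp7a1, the rate-limiting enzyme of bile acid synthesis, which fell by 1.37. The acute phase list had 3 of 23 genes up and 1 down, with Hamp2 up by 3.31 and Apcs by 1.66. Its median of -0.0086 differed in sign from its mean of 0.40 and turned positive under both other scalings (adjusted p = 0.532). Hepatocyte markers did not pass, with a median of 0.0012 and a mean of -0.02 (adjusted p = 0.873), and the sign of the median changed with quantile normalization. The proteasome list did not pass (adjusted p = 0.526), with 1 of 27 genes up, Psmb1 (1.11), a segment gene. Interferon response (adjusted p = 0.437), apoptosis and p53 targets (0.669), cytosolic ribosomal proteins (0.691), cholesterol synthesis (0.846) and markers of endothelial cells (0.694) or of cholangiocytes and stellate cells (0.526) did not pass either.

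Trisomic pre-mid-pachytene spermatocytes differed from euploid ones in 867 of 8384 genes, of which 493 rose and 374 fell, and 2159 had an unadjusted p under 0.05. In the segment, camera with an estimated correlation gave p = 0.107. By Fisher's exact test, which takes the genes as independent, more genes rose there than elsewhere (p = 0.0234). Of the 154 segment genes 16 rose and 2 fell, Arid1b and Zdhhc14, chosen after their values were seen. Among the rising genes were Mapk8ip3, a scaffold of JNK signalling (1.34, SE 0.23, adjusted p = 0.00308), the mitochondrial carrier homologue Mtch1 (1.17, SE 0.20, adjusted p = 0.00304) and Tbl3 (0.84). Elsewhere Crmp1 rose by 2.17 (SE 0.37, adjusted p = 0.00267), the deubiquitinase gene Stambp by 2.06, Auh by 2.00, Ccdc130 by 1.95, Gstm6 by 1.91 and the DNA repair gene Fancg by 1.60. Bhmt, betaine-homocysteine methyltransferase, fell by 3.46 (SE 0.61, adjusted p = 0.00317), Epb41l4b by 3.30 (SE 0.37, adjusted p = 1.7e-04, to a level of 2.70 in the background range), Tmem249 by 3.10, and Tmem190 and Apobec4 by 2.79 each. The whole distribution moved as well: the median change of all tested genes was 0.11 as deposited, 0.05 after quantile normalization and 0.02 after centring. Rising genes made up 56.9% of the changed ones as deposited and 40.6% after centring (326 up, 477 down), so which direction was the more frequent depended on the scaling. The count fell to 247 without trisomic pre-mid-pachytene replicate 1 (123 up, 124 down), 260 without trisomic replicate 2 (120 up, 140 down), 394 without euploid replicate 3 (177 up, 217 down) and 578 without euploid replicate 1 (262 up, 316 down), so the balance also turned with each of these arrays. It was 4 in a fit of these 6 arrays alone, and 35, of which 22 were among the 867, with the round spermatid marker level as a covariate. Under that covariate the median size of the change of the 867 genes was 0.72 instead of 0.86, and their median SE 0.346 instead of 0.216.

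Transcripts typical of round spermatids gave the list with the lowest adjusted p in pre-mid-pachytene spermatocytes. Round spermatid markers fell in 9 of 26 genes and rose in 0 (13 and 1 adjusted over the list alone), with a median of -0.51 and an adjusted p of 4.1e-07 (adjusted p = 0.498 with an estimated correlation). Among them were the acrosomal gene Spaca3 (-2.03), Sun5, which joins the sperm head to the tail (-2.0), and Tex21 (-1.69). Relative to the cell type's mean, the mean of these markers lay at -0.75, -0.37 and -0.02 on the trisomic arrays and at 0.02, 0.69 and 0.43 on the euploid ones. Genes of sperm motility and the axoneme fell in 6 of 25 cases and rose in 2 (8 and 4 adjusted over the list alone), among them Tekt2 (-1.18), a tektin gene of the flagellum. The list had a median of -0.20 and an adjusted p of 0.0109, or 0.065 without euploid pre-mid-pachytene replicate 3, and adjusted p = 0.434 with an estimated correlation. The late haploid genes Prm1 (-0.04) and Tnp1 (-0.07) did not pass, nor did the elongating spermatid list (adjusted p = 0.556), whose median changed sign with the scaling. Of 24 pachytene spermatocyte markers 4 rose (5 adjusted over the list alone) and 0 fell, with Cntd1, a factor of crossover formation, at 1.14, and the list did not pass (adjusted p = 0.669). Early meiotic prophase markers did not pass (adjusted p = 0.896), and their median of 0.13 differed in sign from their mean of -0.02, while Rec8, the meiotic cohesin subunit, fell by 2.12 (SE 0.29, adjusted p = 8.5e-04).

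Lists that rose in the same cells held genes of the segment and of cell metabolism. Of 10 t complex genes, 8 in the segment, 3 rose (7 adjusted over the list alone), with a median of 0.46 and an adjusted p of 0.01, or 0.143 without trisomic pre-mid-pachytene replicate 3, and adjusted p = 0.434 with an estimated correlation. Among them Mas1 rose by 1.24 but did not pass without trisomic replicate 2 (0.97, adjusted p = 0.0721). Proteasome genes rose in 4 of 27 cases and fell in 0 (7 and 0 adjusted over the list alone), with an adjusted p of 0.0109 (adjusted p = 0.594 with an estimated correlation). Psmb7 (0.78) and Psmd7 (0.66) were among them, and neither passed without euploid pre-mid-pachytene replicate 1 or 3 or trisomic replicate 1 or 2 (adjusted p up to 0.134 and 0.141). Oxidative phosphorylation genes rose in 4 of 34 cases and fell in 0 (4 and 0 adjusted over the list alone), with Uqcrc1, a core subunit of complex III, up by 0.83. That list had an adjusted p of 0.0210, or 0.0789 without euploid pre-mid-pachytene replicate 2, and adjusted p = 0.656 with an estimated correlation. After quantile normalization neither the proteasome list (adjusted p = 0.434) nor oxidative phosphorylation (adjusted p = 0.723) passed. Among the other 22 lists tested in these cells, immediate early genes (adjusted p = 0.0502), X-linked housekeeping genes (0.0625), X-linked postmeiotic genes (0.0625), the piRNA pathway (0.107), autosomal retrogenes of X-linked parents (0.438), the meiotic silencing and DNA damage response list (0.839) and Sertoli cell markers (0.776) did not pass. Leydig cell markers had a median level of 5.08 ± 1.71 (SD, n = 3, 3.65 to 6.97) on the euploid arrays and 3.08 ± 0.50 (SD, n = 3, 2.79 to 3.66) on the trisomic ones. Of 5 tested, 1 rose and 1 fell, Scarb1, a receptor of high-density lipoprotein (-0.97), and the list did not pass (adjusted p = 0.484).

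In mid-late-pachytene spermatocytes, with 2 arrays of each genotype, 78 of 8085 genes changed, 46 upward and 32 downward, and 619 had an unadjusted p under 0.05. The homeobox gene Hhex rose by 3.96 (SE 0.34, adjusted p = 1.9e-06), Ttc22 by 3.46 (SE 0.30, adjusted p = 1.9e-06) and Map7d1, which encodes a microtubule-associated protein, by 2.99. The calcium pump gene Atp2c2 fell by 2.96, the transporter gene Slc16a12 by 2.33 and Zbtb8a by 2.31. The phosphatase gene Dusp15 rose by 3.02, or by 1.90 without euploid mid-late-pachytene replicate 2, and Crp, the C-reactive protein gene, fell by 2.69, to a level of 2.79 in the background range, or by 1.66 without that array. Bhmt fell by 4.24 (SE 0.74, adjusted p = 0.00679) to a level of 2.72 in the background range, with an adjusted p of 0.0514 without trisomic replicate 1. Of 144 segment genes 1 rose, Uhrf1bp1 (1.58), which did not pass without trisomic replicate 1 (adjusted p = 0.288) or euploid replicate 2 (1.05, adjusted p = 0.168). The count was 207 without euploid mid-late-pachytene replicate 1 (154 up, 53 down), 165 without euploid replicate 2 (55 up, 110 down), 55 without trisomic replicate 1 (18 up, 37 down) and 46 without trisomic replicate 2 (25 up, 21 down), so which direction was the more frequent depended on single arrays. At a minimum mean of 6 it was 9, and limma on these 4 arrays alone called 0, with 446 at an unadjusted p under 0.05.

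Of 25 lists tested in mid-late-pachytene spermatocytes 3 passed. The t complex list, with 7 of its 9 genes in the segment, had a median of 0.48, though 0 of its genes passed by themselves in limma, also adjusted over the list alone (adjusted p = 0.00621, or 0.078 without euploid mid-late-pachytene replicate 2, and adjusted p = 0.434 with an estimated correlation). Elongating spermatid markers had a median of -0.27, with 0 of 20 genes past the threshold in limma and 1 lower adjusted over the list alone (adjusted p = 0.0210, and adjusted p = 0.891 with an estimated correlation). They did not pass without euploid replicate 1 or trisomic replicate 2 (adjusted p up to 0.312). The mean of the round spermatid markers differed between the euploid arrays themselves, at 0.69 and -0.54 relative to the cell type's mean. Apoptosis and p53 targets had 1 of 9 genes up (2 adjusted over the list alone), Pmaip1, a mediator of p53-dependent apoptosis, by 1.38, with a list median of 0.19 and an adjusted p of 0.0222 (adjusted p = 0.164 with an estimated correlation). The list did not pass without euploid replicate 1 or 2 or trisomic replicate 1 (adjusted p up to 0.136), and Pmaip1 did not pass without trisomic replicate 1 (adjusted p = 0.364) or 2 (adjusted p = 0.0652) or euploid replicate 2 (adjusted p = 0.184). Circadian clock genes (adjusted p = 0.178), early meiotic prophase (0.19) and round spermatid markers (0.245) did not pass.

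Spermatids differed in 68 of 8283 genes, 24 upward and 44 downward, with 720 at an unadjusted p under 0.05. Ttc22 rose by 4.59 (SE 0.24, adjusted p = 2.8e-09) from a level of 2.95 in the background range, the cation channel gene Trpc1 by 2.35, Card19 by 2.22, Mob2 by 2.05 and 4930519F16Rik by 2.04. Bpifb3 fell by 3.28 (SE 0.53, adjusted p = 0.00542), Kcnip2, which encodes a modulator of potassium channels, by 2.76, the aldehyde oxidase gene Aox4 by 2.61, Mroh3 by 2.19, Ndrg4 by 2.06 and the cold receptor gene Trpm8 by 1.72. In the segment 3 of 148 genes rose (Fisher's exact p = 0.00859), led by Mas1, a receptor gene of the angiotensin system, at 2.96 (SE 0.28, adjusted p = 1.2e-05). The others were Stk38 (0.79), not past without euploid spermatid replicate 1 (adjusted p = 0.0604), and Zfp523 (0.69), not past without any 1 of the 6 spermatid arrays (adjusted p up to 0.13). The count was 22 at a minimum mean of 6, 110 without a filter, 121 with the round spermatid marker covariate and 1, Ttc22, in a fit of the spermatid arrays alone.

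Of 25 lists tested in spermatids 4 passed. The t complex list, 8 of its 10 genes in the segment, had a median of 0.38 with 1 gene up (2 adjusted over the list alone) and an adjusted p of 8.7e-04 (adjusted p = 0.333 with an estimated correlation). Xenobiotic metabolism had a median of -1.02 over 7 genes, with 1 down (2 adjusted over the list alone), and an adjusted p of 0.00112, or 0.459 without trisomic spermatid replicate 2, and adjusted p = 0.434 with an estimated correlation. On that array the mean of the Sertoli cell markers lay at -1.08 relative to the cell type's mean, against -0.34 to 0.47 on the other 5. Leydig cell markers had a median level of 5.50 ± 2.50 (SD, n = 3, 2.81 to 7.75) in euploid spermatids and 3.57 ± 1.28 (SD, n = 3, 2.83 to 5.05) in trisomic ones. Elongating spermatid markers had a median of -0.25 with 0 of 20 genes past the threshold in limma, also adjusted over the list alone (adjusted p = 0.0330, and adjusted p = 0.91 with an estimated correlation). They did not pass without euploid spermatid replicate 1 or 3 or trisomic replicate 2 (adjusted p up to 0.631). Proteasome genes had a median of 0.09 with 0 of 27 past the threshold in limma and 1 higher adjusted over the list alone (adjusted p = 0.0457, and adjusted p = 0.738 with an estimated correlation). That call was lost after quantile normalization (adjusted p = 0.0678) and with the replicate block (adjusted p = 0.0749). It was also lost without euploid or trisomic spermatid replicate 1, euploid spermatid replicate 3, trisomic spermatid replicate 2, any euploid liver array or trisomic liver replicate 1 or 2 (adjusted p up to 0.184). Round spermatid markers had a median of -0.03 and did not pass.

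The changes were compared between cell types. Mid-late-pachytene spermatocytes and spermatids shared 4 rising genes, 1700097N02Rik, Npepl1, Runx1t1 and Ttc22, where 0.0706 were expected if the calls were independent (Fisher's exact adjusted p = 3.4e-06). They also shared 5 falling genes, 4921536K21Rik, Bcr, Bhmt, Pard6g and Ramp3, where 0.0391 were expected (adjusted p = 2.6e-09). These shared genes other than Ttc22, Bhmt and Pard6g were chosen after their values were seen. The calls of the cell types are not fully independent, since they use the same spread per gene. A gene with a small spread passes more easily in each, which these p values do not allow for. Liver and pre-mid-pachytene spermatocytes shared 15 rising and 3 falling genes, where 16.03 and 3.66 were expected, and the overlap of the other pairs was not beyond chance. In liver the deviations from the genotype means correlated most across genes between arrays of equal replicate number (r = 0.11, 0.31 and 0.15). The labels give no pairing, and spermatids had r = -0.01, 0.39 and -0.13 for equal numbers, so a pairing is not established. With the replicate number as a block, 774 liver genes passed, 636 of them among the 781, and 22 lists passed. In the other cell types the block gave 822, 61 and 73 genes for pre-mid-pachytene spermatocytes, mid-late-pachytene spermatocytes and spermatids. Of the named genes, 3 of 79 in liver, 10 of 72 in pre-mid-pachytene spermatocytes, 4 of 62 in mid-late-pachytene spermatocytes and 1 of 64 in spermatids no longer passed with the block. Among them were Fads2 in liver, Psmd7 in pre-mid-pachytene spermatocytes and Zfp523 in spermatids.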

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

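The tests on genes of similar level, on removal of the stage differences, on position along chromosome 16, on strain variants and on the round spermatid marker covariate, and the division of the splits by the genotypes they kept, were chosen after the results were seen. Differences between cell types below passed an interaction test of the difference itself unless stated otherwise.

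The shift of the trisomic segment differed from that in liver by -0.59 in pre-mid-pachytene spermatocytes, -0.40 in mid-late-pachytene spermatocytes and -0.35 in spermatids, and it was larger in spermatids than in pre-mid-pachytene spermatocytes by 0.24 (SE 0.054). A lower level of the segment genes in germ cells was argued against by genes of similar level in both cell types, whose differences to liver were -0.71 (SE 0.063, 41 genes), -0.35 (SE 0.075, 23 genes) and -0.29 (SE 0.072, 23 genes). A mix of stages along the differences between the sorted germ cell types was argued against as the whole cause for pre-mid-pachytene spermatocytes. There the removal of the changes that follow these differences (18.1% of the variance) left a difference of -0.60 (SE 0.050). The removal does not cover somatic cells or stages outside these differences. Cells of other stages stay open for mid-late-pachytene spermatocytes and spermatids. In these the removal took only 0.215% and 3.11% of the variance and left -0.39 and -0.35. A stage-dependent output of the extra copy and a general compression of differences on the germ cell arrays were not tested and stay open.

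For the differences to liver, 9 of 100 drawn splits of the genotypes within both cell types gave a difference as large as the real one of 0.59 for pre-mid-pachytene spermatocytes (highest other 0.75) and 30 of 100 as large as that of 0.35 for spermatids (highest other 0.86). These shares decide nothing, since 9 and 10 of the splits kept the liver genotypes and with them the real liver shift, and each of those gave a difference as large. Among the splits that kept neither cell type's genotypes, 0 of 84 were as large for pre-mid-pachytene spermatocytes (highest 0.38) and 16 of 82 for spermatids (highest 0.45). The splits of this kind still mix the genotypes unevenly, so they keep part of the shift in both cell types. In liver the median size of the segment shift over the other splits was 0.23. The shares of 84 and 82 therefore do not show differences without a genotype effect, and no conclusion is drawn from them.

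Chromosome 16 genes shifted differently from liver by -0.26 in pre-mid-pachytene spermatocytes, -0.12 in mid-late-pachytene spermatocytes and -0.12 in spermatids, and the pre-mid-pachytene shift differed from those of mid-late-pachytene spermatocytes and spermatids by 0.14 each. A mix of stages along the differences between the sorted germ cell types was argued against as the whole cause. The shift of -0.22 in pre-mid-pachytene spermatocytes remained at -0.19 (SE 0.023) after removal of the changes that follow stage. With the round spermatid marker covariate it was -0.14 (limma adjusted p = 0.00365). Strain variants under the probes were argued against by a liver shift of 0.015 (SE 0.028) over the 155 genes scored in both cell types. The genes nearest the centromere lay lower than those farthest from it by -0.64 (SE 0.105), which is consistent with a position-dependent lower output and may point to the centromeric part of the chromosome, as a hypothesis. Whether this part differs in copy number, pairing or chromatin between the germ cells of the genotypes was not tested.

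The shift of chromosome 10 differed between spermatids and pre-mid-pachytene spermatocytes by -0.065. Among the named genes tested in both cell types, the change differed from that in liver for 25 of 71 in pre-mid-pachytene spermatocytes, 11 of 61 in mid-late-pachytene spermatocytes and 9 of 58 in spermatids. It differed from that in pre-mid-pachytene spermatocytes for 2 of 101 in mid-late-pachytene spermatocytes and 3 of 105 in spermatids. The named genes were mostly chosen for large changes, and the shares over all genes tested in both were lower: 339 of 6510, 56 of 6058 and 59 of 6006 against liver, and 8 of 7434 and 18 of 7401 against pre-mid-pachytene spermatocytes. Of the segment genes, 10 of 128, 3 of 117 and 3 of 116 differed from liver, with the smaller value in the germ cells for 10, 3 and 2 of them.

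Probe sets without a gene name were not part of the gene tests. Tested in the same way, 30 of 367 passed in liver (23 higher, 7 lower), 22 of 366 in pre-mid-pachytene spermatocytes (12 and 10), 7 of 348 in mid-late-pachytene spermatocytes (2 and 5) and 4 of 341 in spermatids (2 and 2). With at most 3 arrays in a group, single arrays were not tested as outliers.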

How the results depend on the processing

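The stage covariate and the chromosome 16 shift were added after the data were seen, and the other alternatives were planned. Over 17 results, 119 of 128 values with an array left out and 121 of 135 under the other settings counted as unchanged. For counts this meant staying within 1.5 times, and for other values keeping the side of the threshold. A change of sign was counted only where a value passed, so the spermatid X shift, from -0.12 to 0.10, counted as unchanged. With only the arrays of the cell type, 19 genes passed in liver, 4 in pre-mid-pachytene spermatocytes, 0 in mid-late-pachytene spermatocytes and 1 in spermatids. In mid-late-pachytene spermatocytes limma had 446 at an unadjusted p under 0.05. These fits had fewer arrays to estimate the spread. The shared spread can also be too small for liver genes, since it draws on germ cell arrays, where hepatocyte markers lay between 2.33 and 2.45. Hsd3b5 had an SE of 1.36, while its SD was 4.86 over the 3 trisomic liver arrays. Which of these lowered the counts was not tested. The X shift in liver, 0.080, passed on the liver arrays alone (limma adjusted p = 0.0270). The stage covariate gave 35 genes in pre-mid-pachytene spermatocytes, 150 in mid-late-pachytene spermatocytes and 121 in spermatids. For the first of these the median SE of the 867 genes grew from 0.216 to 0.346 while the median size of their change went from 0.86 to 0.72. A minimum mean of 6 gave 9 genes in mid-late-pachytene spermatocytes and 22 in spermatids, and no filter gave 110 in spermatids. The pre-mid-pachytene segment shift passed at a minimum mean of 4 (0.13) and with the mean over genes (0.15), and 0 of 105 list tests passed with an estimated correlation (22 at the preset one). The cause of the other changes was not tested.

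Leaving out arrays, the counts ranged from 580 (without euploid replicate 3) to 922 (without euploid replicate 1) in liver, from 247 (without trisomic replicate 1) to 1089 (without euploid replicate 2) in pre-mid-pachytene spermatocytes, from 46 (without trisomic replicate 2) to 207 (without euploid replicate 1) in mid-late-pachytene spermatocytes, from 54 to 88 in spermatids and from 18 to 26 for lists. The pre-mid-pachytene segment shift ranged from 0.070 to 0.14, and the others from 0.69 to 0.72 in liver, 0.28 to 0.34 in mid-late-pachytene spermatocytes and 0.33 to 0.40 in spermatids. Differences to liver stayed between -0.63 and -0.56, -0.42 and -0.37, and -0.37 and -0.31. The X shift in mid-late-pachytene spermatocytes ranged from -0.71 (without euploid replicate 2), a reversal, to 0.84 (without euploid replicate 1), and the cause was not tested. The chromosome 16 shift in pre-mid-pachytene spermatocytes ranged from -0.25 to -0.20, and was -0.14 with the stage covariate.

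Of the named genes past the threshold, 53 of 65 in liver, 24 of 60 in pre-mid-pachytene spermatocytes, 8 of 18 in mid-late-pachytene spermatocytes and 13 of 20 in spermatids passed without any 1 array. Over 277 named results, 1320 of 1538 values with an array left out and 2074 of 2357 under other settings kept their side of the threshold. A change of sign was counted only where a value passed, and by that rule 0 reversed. Genes with a group in the background range, such as H19 in euploid liver, have changes that depend on the floor of the array.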

Other observations

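The tests below on the sex-dependent genes, the hepatocyte markers, the removal of stage differences and the marker covariate were chosen after the result was seen, while the splits of the genotypes were planned, except those for chromosome 16.

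In trisomic liver 4 of 6 female-biased genes rose, 7 of 11 male-biased genes fell and 6 genes did not pass, with the male-biased Susd4 at 0.98, and the list as a whole did not pass camera (adjusted p = 0.19). The counts rest on single liver arrays: 4 male-biased genes fell without euploid replicate 1 or 3, 3 female-biased genes rose without euploid replicate 3 or trisomic replicate 2 or 3, and without trisomic replicate 2, which lay farthest out, the male-biased median was -1.88 instead of -3.04. Arrays of female animals under male labels were argued against by the Y-linked gene Eif2s3y, whose lowest level on a trisomic liver array was 11.5. A lower share of hepatocyte RNA would lower the female-biased genes, which rose (median 3.84, SE 1.27). That rise was known beforehand and does not bear on the male-biased genes. For the fall of the male-biased genes, a lower share was argued against as the cause of changes this large by the hepatocyte markers. These had a median change of 0.0012 (SE 0.0435) over 22 and of -0.15 (SE 0.164) over the 7 with a euploid level below 15. The 22 had a median level of 15.66 in euploid liver, near the highest value of 16.75, where a small fall could be missed. Peritubular and stromal markers changed by 0.75 (SE 0.15), cholangiocyte and stellate cell markers by 0.35 (SE 0.17) and macrophage and leukocyte markers by 0.34 (SE 0.30). Endothelial cell markers changed by -0.04 (SE 0.17). A smaller fall of the hepatocyte share therefore stays open. These lists did not move apart beyond their spread (largest difference 0.79, SE 0.285, Holm-adjusted p = 0.303), which does not decide it. A shift of the sex-dependent programme of the liver is a hypothesis that these genes raised and that was not tested on others, and hormone levels, which set this programme and are not part of these data, and an effect of genes in the segment stay open.

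The round spermatid markers passed camera downward in trisomic pre-mid-pachytene spermatocytes, but not with an estimated correlation (adjusted p = 0.498), and the highest trisomic array (-0.02) lay next to the lowest euploid one (0.02). The changes along the stage differences made up 18.1% of the variance of the changes there, against 0.215% in mid-late-pachytene spermatocytes and 3.11% in spermatids. Removing them took the X shift in pre-mid-pachytene spermatocytes from -0.27, itself -0.11 without trisomic replicate 2 and -0.45 without trisomic replicate 3, to 0.01, and the segment shift from 0.11 to 0.10. With the round spermatid marker level as a covariate 35 genes passed, 22 of them among the 867. The median size of the change of the 867 genes was 0.86 before and 0.72 with the covariate, while the median SE grew from 0.216 to 0.346, and 854 kept their direction. The covariate followed genotype (r = -0.797 over the 6 arrays), and the spread grew by more than the changes shrank, so the lost calls do not show that the changes went away. How many of the changes come from another mix of stages stays open.

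Other splits of the 6 arrays of a cell type into 3 and 3 put arrays of both genotypes in each group. The mix is uneven, so they keep part of the genotype effect and do not show values without it. In liver the median size of the segment shift over the other splits was 0.23, against the real 0.70. The 10 splits are too few for a share under 0.05. In liver the real split gave 781 genes and the highest other 142, and the other splits that part all 3 pairs of equal replicate number gave 31, 11 and 57. Pre-mid-pachytene spermatocytes had 867 against 53, and spermatids 68 against 42. For the segment shift the real value and the highest other were 0.70 and 0.27 in liver, 0.11 and 0.11 in pre-mid-pachytene spermatocytes, and 0.35 and 0.18 in spermatids. Chromosome 16 in pre-mid-pachytene spermatocytes had a size of 0.22 against 0.12. In each of these, and for the X in liver (0.08 and 0.08), 1 split, the real one, gave a value as large. For the X, 4 of 10 splits gave a value as large in pre-mid-pachytene spermatocytes (0.27, highest other 0.37) and 10 of 10 in spermatids (highest other 0.25). For the lists, 4 of 100 drawn splits gave 22 or more, the real one included. That share is under the planned 0.05 but close to it, and 100 draws fix it only roughly, so chance is not excluded. The highest other split gave 23 and the median of the others was 13, so many lists pass camera at the preset correlation in other splits too.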
